A study of Sus scrofa with 6 samples.

How the data were processed

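RNA sequencing was done on oocytes of prepubertal gilts whose ovaries came from an abattoir. Per the labels' protocols, RNA of oocytes freed of cumulus cells was made into libraries with a directional kit. The protocol gives 360 oocytes with 3 replicates, without saying whether that number is per group or in all. Samples were grouped by follicle size as their titles give it, into large (3 libraries) and small (3 libraries).

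The authors deposited a table of 19296 rows with whole-number read counts per gene for each library, beside TPM values that sum to the same total in each library. The counts are as deposited and not normalised, and the deposited TPM values were made by the authors from gene length and depth. The genome build was Sscrofa11.1, per the submitters' processing notes. The aligner, the counter, the annotation release and the use of strand in counting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart. Total counts ranged from 8015357 to 56887282. Counting error is larger in large-follicle library 3, the shallowest.

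A date stands as gene name in 25 rows. They were left out of library sizes and tests, with a mean of 0.153% of the reads. Of 4604 rows named by an Ensembl identifier, 875 had a symbol in the name table used and 853 were given it, since the rest would have repeated a name in the table. Gene positions come from a RefSeq gene table of the same assembly, matched by symbol where that symbol occurs once there. NLRP5 and DPPA3 were not analysed here.

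The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM factors, filterByExpr and robust estimation, on group alone, with 14091 genes tested. Log2 differences are large minus small follicles, their SE is the absolute log2 difference divided by the square root of F, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 23 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. Neither of these called any of the 23 lists at 0.05. Summed levels of markers of other cells were compared by an exact two-sided permutation test.

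The 23 lists, fixed before the data were examined, were oocyte secreted factors and zona, oocyte transcription factors, maternal effect genes, meiotic cell cycle, meiotic arrest signalling, chromatin modifiers, maternal mRNA translation and decay, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded transcripts, ribosome biogenesis, proteasome, cholesterol synthesis, fatty acid and lipid droplet metabolism, glycolysis, antioxidant genes, DNA repair, apoptosis, TGF-beta receptors and SMADs, contact of oocyte and cumulus cells, and markers of granulosa and cumulus, theca and stromal, and blood, immune and endothelial cells. The rule for named genes was fixed then too. It takes the 12 genes with the largest difference per direction among those that passed, with a symbol, no overlap of groups and at least 5 CPM in the higher group, and, if under 10 passed, the 10 next by p. It adds up to 4 passing members per list, or else the 2 with the smallest p. It also adds GDF9, BMP15, ZP3, ZP4, NLRP5, DPPA3, ZAR1, BTG4, CCNB1, CDK1, MOS, WEE2, DNMT1, FIGLA, KIT, GJA4, FSHR, INHBA and COL1A2, and the 5 genes with the highest mean. Other list members named as past the adjustment over their list were named after their values were seen.

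The 5 genes with the highest mean were DNMT1, ACCSL (8730 ± 619 and 9157 ± 402 CPM), UHRF2 (5162 ± 424 and 5307 ± 332 CPM), SIN3A (4140 ± 214 and 3584 ± 53.8 CPM) and NUP214 (4016 ± 876 and 3437 ± 361 CPM), given as mean ± SD in large-follicle and small-follicle oocytes. Of list members named by the rule that did not pass, PDE8A differed by 0.27 (SE 0.078), PRKAR1B by -0.60 (SE 0.18), PSMC6 by -0.80 (SE 0.22), PSMC2 by 0.20 (SE 0.067), SQLE by 0.27 (SE 0.074), HSD17B7 by 0.42 (SE 0.13), MPC1 by -0.48 (SE 0.12) and PDHA1 by 0.26 (SE 0.081) on the log2 scale. Likewise XIAP differed by 0.33 (SE 0.090), MCL1 by -0.48 (SE 0.14), ACVR1B by 0.27 (SE 0.072), BMPR1A by 0.29 (SE 0.086), PTGS2 by -1.27 (SE 0.48), FDX1 by -0.17 (SE 0.12), FBLN1 by 0.36 (SE 0.12) and KDR by 0.89 (SE 0.52). PTGS2 (0.262 and 0.797 CPM in large-follicle and small-follicle oocytes) and KDR (0.397 and 0.206 CPM) had very few reads.

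Counts of the same gene differed between libraries of a group by more than sampling noise (chi-square per degree of freedom 10.4 to 22.2), so none was treated as another deposited again. This does not show that the replicates were separate collections. The scripts were tested on simulated counts for this comparison, 3 libraries against 3, with 13954 genes in the step. edgeR recovered 32 of 67 genes changed 1.5-fold, 47 of 67 changed 2-fold and 57 of 66 changed 4-fold, with 11 false calls among 13851 unchanged genes. DESeq2 recovered 38, 49 and 59, with 27 false calls. The list that was shifted was found, and 0 of 20 unchanged lists were called. Simulated genes were drawn independently, so this does not show how camera's preset correlation behaves with correlated genes. In the real data the estimated correlation was 0.600 for nuclear oxidative phosphorylation, 0.648 for cytosolic ribosomal proteins and 0.725 for mitochondrially encoded transcripts.

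Alternatives were DESeq2 (version 1.42.0), edgeR's likelihood ratio test, limma-voom, DESeq2's size factors in edgeR, library size alone, other filters and thresholds, limma-trend on log2(TPM + 1) and with pseudocounts of 0.1 and 0.5, the replicate number as a block, and each library left out in turn. Thinning of all libraries to the shallowest and a correction for gene length per library (a smoother of span 0.3 on the relative length that counts and TPM give) were added after seeing the data. The mean deviation of granulosa and cumulus markers in each library was fitted beside the group to the mean deviation of each other list, also after seeing the data. For the tests of dilution the germline-restricted genes were chosen from what is known of them, after related values were seen: ZP2, ZP3, ZP4, GDF9, BMP15, OOSP2, ASTL and IZUMO1R of the zona and secreted factor list, PADI6, NLRP13, ZAR1, ZAR1L, NPM2, NLRP9, DPPA5 and OOEP of the maternal effect list, and FIGLA, NOBOX, LHX8, SOHLH2, TBPL2, YBX2 and SALL4 of the transcription factor list. GC content was not analysed here. The result of a single gene in a lysosomal list used in the closing section is not reported here.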

Results

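Messenger RNA was counted in pig oocytes taken from large antral follicles, 3 to 6 mm across, and from small antral follicles, 1.5 to 1.9 mm across, of prepubertal gilts. The cumulus cells that surround an oocyte had been removed before RNA was isolated. The series asks how the transcripts of oocytes with different developmental competence differ, and follicle size is the only contrast its labels give. Each group had 3 libraries. Total counts were 21456499, 56887282 and 8015357 in large-follicle libraries 1, 2 and 3, and 55342036, 33298449 and 39752927 in small-follicle libraries 1, 2 and 3. Nothing in the labels says whether the replicates were separate collections of ovaries, so the p-values measure the spread between these libraries, which may be technical. The first principal component, with 39.2% of the variance, set large-follicle library 3 (score 54.5) apart from the other libraries (-15.0 to -6.03).

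In oocytes from large follicles 2 genes rose and 7 fell, among 14091 tested. ALOX15B, a lipoxygenase that oxygenates polyunsaturated fatty acids, rose 1.80-fold, from 17.8 ± 1.81 to 32.0 ± 1.63 CPM (read counts scaled to library size; mean ± SD, n = 3 per group). PSAP, the precursor of the saposins that help lysosomal enzymes break down sphingolipids, fell by 0.85 on the log2 scale (SE 0.11), from 106 ± 7.92 to 59.3 ± 8.73 CPM. MFSD12, a lysosomal membrane transporter, fell by 0.71 (SE 0.083) on that scale, and RABEP2, an effector of endosomal Rab proteins, fell by 0.72 (SE 0.098). The core RNA polymerase II subunit gene POLR2B fell by 0.70 (SE 0.095), to 18.5 ± 1.60 CPM from 29.7 ± 0.177 CPM. The phosphatase activator gene PTPA fell by 0.70 (SE 0.091), the dynein adaptor gene BICDL1 by 0.68 (SE 0.087) and ZFYVE27, which encodes an endoplasmic reticulum protein, by 0.58 (SE 0.076). The other gene that rose, ENSSSCG00000012006, had no name in the tables used here and was singled out after its values were seen. It stood at 65.6 ± 17.5 CPM in large-follicle and 20.9 ± 2.85 CPM in small-follicle oocytes, a log2 difference of 1.65 (SE 0.20).

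**Figure D1:**
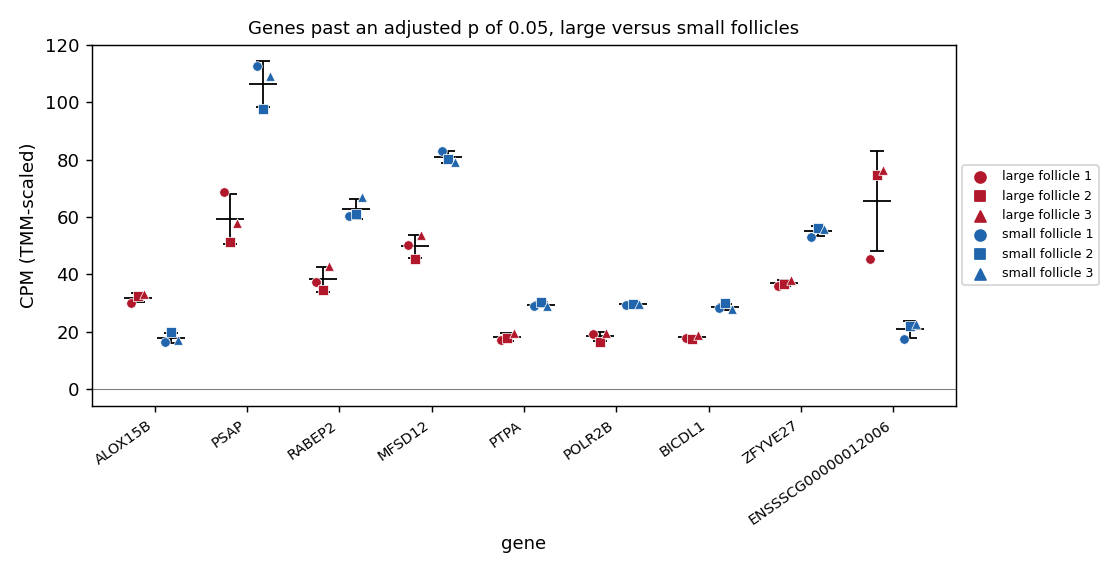
CPM scaled by TMM (vertical axis) of the genes that passed the threshold, 1 point per library, with red for large and blue for small follicles and black bars for the mean and SD of 3 libraries. Every large-follicle library lies on one side of every small-follicle library for each gene, as for PSAP, at 51.4 to 68.7 against 97.6 to 113 CPM.

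In assembly Sscrofa11.1, PSAP lies on chromosome 14 from 74734185 to 74820645, BICDL1 on chromosome 14 from 40004464 to 40125541 and ZFYVE27 on chromosome 14 from 109088758 to 109119854. RABEP2 lies on chromosome 3 from 18568264 to 18586259, MFSD12 on chromosome 2 from 75098531 to 75120795, PTPA on chromosome 1 from 269401776 to 269431465 and POLR2B on chromosome 8 from 56232730 to 56283367. The 10 genes next in order did not pass, and all had lower means in large-follicle oocytes: CILP, GMEB2, MNT, NSUN5, RNF167, RNF31, RETREG3, SLC25A15, NAAA and TMEM129. Their log2 differences lay between -0.85 (RETREG3) and -0.59 (TMEM129), with adjusted p of 0.0522 to 0.0677 by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 2539 genes, of which 1388 had higher and 1151 lower means in large-follicle oocytes, against 704.6 by chance if the p-values are exact. Other splits of the 6 libraries into 3 and 3 gave 173 to 1786 such genes.

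All 9 calls had the same adjusted p of 0.0499 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, just under the threshold of 0.05, and with DESeq2's size factors in edgeR their adjusted p was 0.0535 and 0 genes passed, with 2525 at an unadjusted p under 0.05, while DESeq2's own test called 722. Without large-follicle library 3 the count was 1899 and without large-follicle library 1 it was 77, and each held all 9 genes. Without large-follicle library 2 or small-follicle libraries 1, 2 or 3, edgeR called 0 genes, with 1881, 1533, 1448 and 1918 at an unadjusted p under 0.05, and DESeq2 called 262, 108, 111 and 223.

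The list for the zona pellucida, the coat of the egg, and for factors the oocyte secretes was lower as a set in large-follicle oocytes. It also held KIT, CD9 and IZUMO1R, which encode surface proteins, and KITLG, counted here among granulosa and cumulus markers too. The list had 15 tested members, every one with a lower mean in large-follicle oocytes, and its mean log2 difference was -0.42 (SE over genes 0.079; limma's camera, adjusted p = 3.92e-07). With an estimated correlation between genes the list's adjusted p was 0.437 by camera. With the preset correlation it passed without each single library, with means of -0.51 to -0.37, and at a filter of 5 CPM, with a mean of -0.34. ZP3, which encodes a zona protein, stood at 2093 ± 363 CPM in large-follicle and 3102 ± 184 CPM in small-follicle oocytes (n = 3 each), a log2 difference of -0.57 (SE 0.12). BMP15, a growth factor by which the oocyte acts on its cumulus cells, stood at 2881 ± 236 and 3851 ± 133 CPM (log2 difference -0.42, SE 0.080), and ASTL, the protease that hardens the zona after fertilisation, at 452 ± 47.6 and 620 ± 22.3 CPM (-0.46, SE 0.087). No member passed over all genes tested. Adjusted over the list alone, 7 fell: ASTL, BMP15, ZP3, KIT, ZP4, CD9 and ZP2, with CD9 under 1 CPM in both groups. WFDC2, also under 1 CPM in both groups, had a log2 difference of -1.07 (SE 0.71) and did not pass. GDF9, the partner of BMP15, had a log2 difference of -0.23 (SE 0.096) and did not pass either adjustment. The list's mean deviation from the average of all libraries was -0.29, -0.28 and -0.052 in large-follicle libraries 1, 2 and 3, and 0.15, 0.27 and 0.20 in small-follicle libraries 1, 2 and 3.

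**Figure D2:**
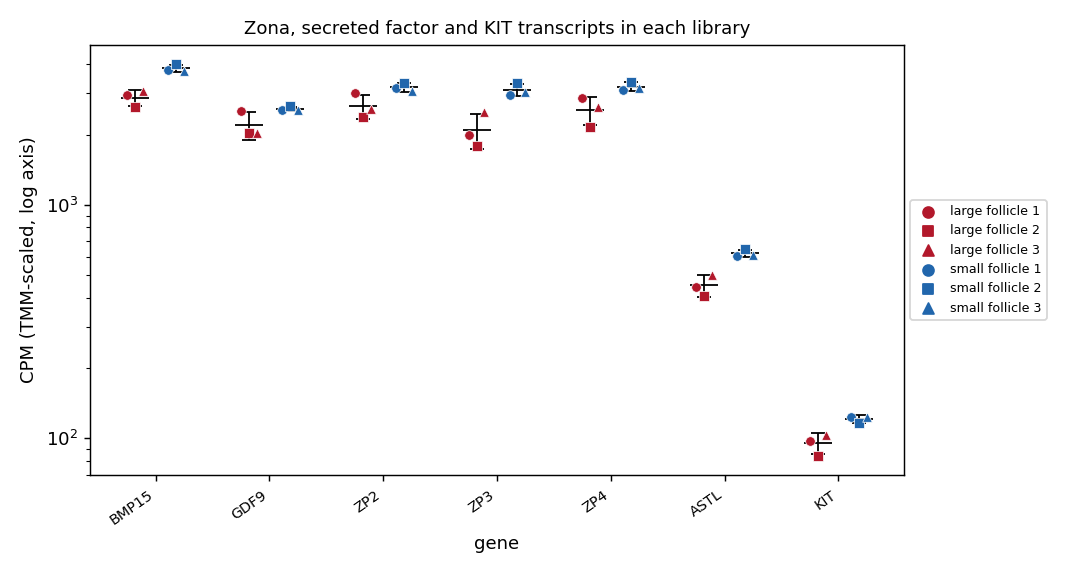
CPM scaled by TMM (vertical log axis) of zona, secreted factor and KIT transcripts, 1 point per library, with red for large and blue for small follicles and black bars for the mean and SD of 3 libraries. ZP3 lies at 1790 to 2495 CPM in large-follicle and 2965 to 3311 CPM in small-follicle libraries.

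Chromatin modifier transcripts had a higher mean as a set in large-follicle oocytes, with a mean log2 difference of 0.11 (SE over genes 0.032) over 49 tested members, 35 of them with higher means (camera, adjusted p = 0.00160; adjusted p = 0.789 with an estimated correlation). Taken over libraries, the SE of that difference was 0.067. The list passed without each single library, with means from 0.066 without large-follicle library 2 to 0.16 without large-follicle library 3. The histone demethylase gene KDM1B, which acts in setting maternal imprints, stood at 209 ± 6.27 CPM in large-follicle and 164 ± 6.99 CPM in small-follicle oocytes (n = 3 each), a log2 difference of 0.35 (SE 0.070). EZH2, the catalytic subunit of the Polycomb repressive complex, differed by 0.38 (SE 0.084). No member passed over all genes. Adjusted over the list alone, 8 rose (KDM1B, EZH2, SMARCA5, DNMT3B, CHD1, KDM5A, CHD4 and SETDB1) and EED, a partner of EZH2, fell by 0.76 (SE 0.20). DNMT1, the maintenance DNA methyltransferase, was the most abundant transcript measured, at 25434 ± 2940 and 21119 ± 1237 CPM, and its difference of 0.27 (SE 0.097) did not pass. Large-follicle library 3 stood below the average of all libraries for this list, at -0.066, with large-follicle libraries 1 and 2 at 0.092 and 0.13.

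The meiotic cell cycle list also passed, with a mean log2 difference of 0.039 (SE over genes 0.035) over 42 tested members, 27 of them with higher means (camera, adjusted p = 0.0435; adjusted p = 0.789 with an estimated correlation). Adjusted over the list alone, SMC1B, a meiosis-specific cohesin subunit, rose with a log2 difference of 0.39 (SE 0.076), from 145 ± 8.33 to 189 ± 9.84 CPM (n = 3 each), and GTSE1, a microtubule-binding protein, fell by 0.33 (SE 0.080). No member passed over all genes. The kinase genes WEE2 (0.21, SE 0.077) and MOS (-0.040, SE 0.081), the cyclin gene CCNB1 (0.11, SE 0.067) and CDK1 (-0.045, SE 0.093) did not pass either adjustment. Scaled to library size alone the list's mean was -0.010 and its adjusted p 0.0927 by camera. The call was also lost without large-follicle library 1, small-follicle library 1 or small-follicle library 2 (adjusted p = 0.219, 0.0786 and 0.0533 by camera). It was lost too at a filter of 5 CPM (0.0760) and with the replicate number as a block (0.0641). Thinning all libraries to the shallowest, a setting chosen after seeing the data, also ended it (0.0596).

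Transcripts of oxidative phosphorylation, of the cytosolic ribosome and of the mitochondrial genome had lower means as sets in large-follicle oocytes. With the SE taken over libraries, the group differences were -0.16 (SE 0.12), -0.11 (SE 0.13) and -0.28 (SE 0.31) in that order. None of them clearly exceeded the spread between libraries. Nuclear-encoded subunits of oxidative phosphorylation had a mean log2 difference of -0.16 (SE over genes 0.018) over 67 tested members, 55 of them with lower means (camera, adjusted p = 7.41e-06; adjusted p = 0.789 with an estimated correlation). The list passed without each single library, with means of -0.10 without large-follicle library 1 or 2 and -0.27 without large-follicle library 3. UQCRC2, a subunit of respiratory complex III, stood at 5.44 ± 1.30 CPM in large-follicle and 8.63 ± 0.414 CPM in small-follicle oocytes (n = 3 each), and NDUFA11, of complex I, at 23.9 ± 2.81 and 31.9 ± 4.35 CPM. Cytosolic ribosomal proteins had a mean of -0.11 (SE over genes 0.021) over 59 members (adjusted p = 0.0272; adjusted p = 0.845 with an estimated correlation), with RPS21 at -0.51 (SE 0.12) and RPLP1 at -0.50 (SE 0.17). The 13 mitochondrially encoded transcripts had a mean of -0.28 (SE over genes 0.058; adjusted p = 0.0469, and 0.789 with an estimated correlation), with ATP8 at -0.63 (SE 0.25) and ND3 at -0.62 (SE 0.27). No member of these lists passed over all genes or adjusted over the list alone. Large-follicle library 3 stood above the average of all libraries for oxidative phosphorylation (0.15) and ribosomal proteins (0.19), whereas large-follicle libraries 1 and 2 stood below it (-0.19 and -0.19, and -0.15 and -0.20). In small-follicle libraries 1, 2 and 3 the deviations were 0.028, 0.17 and 0.035 for oxidative phosphorylation and 0.061, 0.13 and -0.033 for ribosomal proteins. Granulosa and cumulus markers deviated by -0.28, -0.21 and 0.24 in the large-follicle and 0.70, 0.28 and -0.73 in the small-follicle libraries. They had the sign of the ribosomal proteins in all 6 libraries, and of oxidative phosphorylation and of the mitochondrially encoded transcripts in 5 each. The ribosomal protein call was lost without large-follicle library 1, large-follicle library 2 or small-follicle library 2 (means -0.056, -0.033 and -0.073; adjusted p = 0.318, 0.765 and 0.214 by camera), and these genes have many processed copies with which the authors' counting could share reads. The mitochondrial mean was 0.0073 without large-follicle library 2, whose mitochondrial share of reads was 0.590% against 0.970% to 1.33% in the others, and that call was also lost without small-follicle library 1 or 2 (adjusted p = 0.0794 and 0.164), with library size alone (0.103), without a filter (0.0608) and at 5 CPM (0.0511). A correction for gene length in each library, also chosen after seeing the data, ended both the ribosomal protein and the mitochondrial call (means -0.081 and -0.25; adjusted p = 0.0990 for each by camera), with 76.6% and 87.8% of the means kept.

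**Figure D3:**
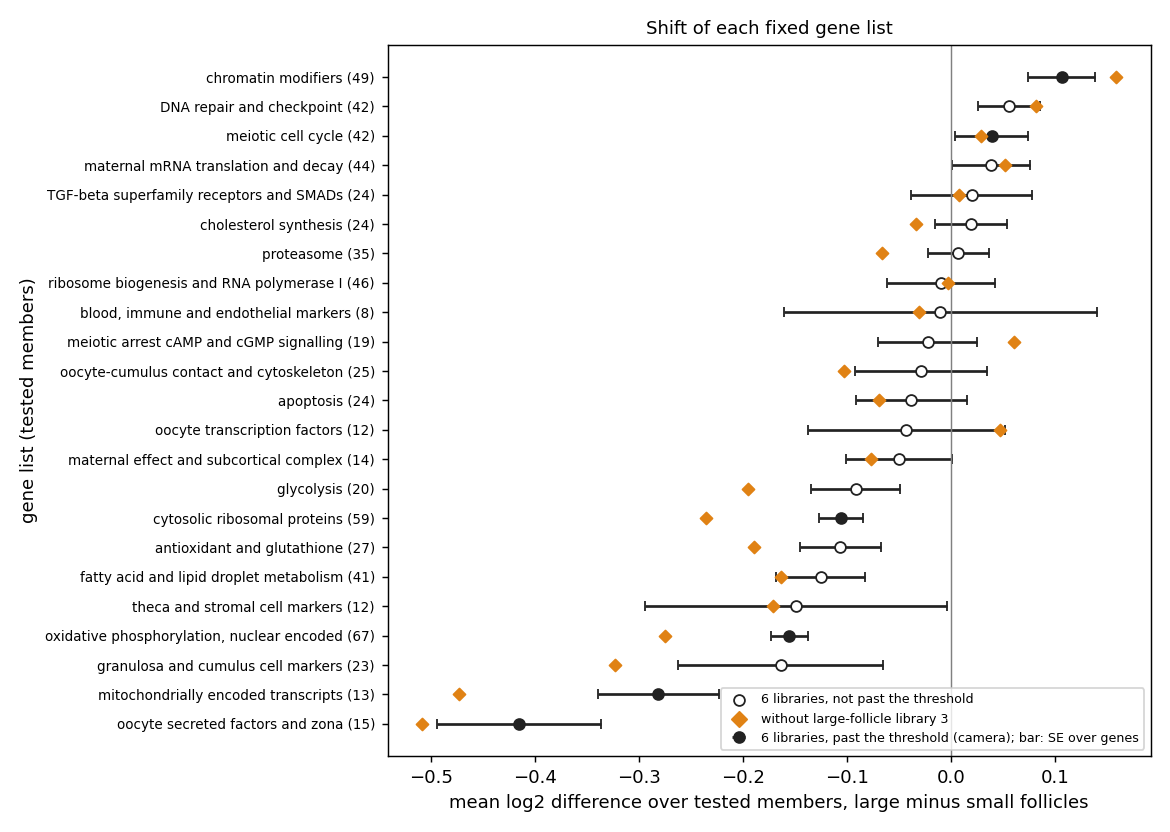
Mean log2 difference, large minus small follicles, over the tested members of each of 23 gene lists (horizontal axis), with the number of tested members after each name. Circles with bars give the mean and SE over genes in 6 libraries, filled where camera's adjusted p passed the threshold, and diamonds give the mean without large-follicle library 3. The zona and secreted factor list lies lowest at -0.42 and the chromatin modifier list highest at 0.11.

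Without large-follicle library 3, an alternative chosen after seeing the data for list members, 19 chromatin modifier genes rose and 1 fell, 25 oxidative phosphorylation and 17 ribosomal protein genes fell and 0 rose, and 4 zona and secreted factor genes fell. In that comparison 10 genes of the list for translation and decay of maternal mRNA rose and 0 fell, and 8 meiotic cell cycle genes rose and 3 fell. As sets, the lists for maternal mRNA (mean 0.052), DNA repair (0.081), glycolysis (-0.20) and antioxidant genes (-0.19) passed there too (adjusted p = 0.0309, 0.0308, 0.0323 and 0.0309 by camera). In all 6 libraries the glycolysis and antioxidant lists deviated with the sign of the granulosa and cumulus markers (correlations 0.882 and 0.704). These calls come from 2 large-follicle against 3 small-follicle libraries.

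The other 17 lists did not pass as sets. Ribosome biogenesis (46 tested members, mean -0.0095, adjusted p = 0.203 by camera) held genes that moved both ways: adjusted over the list alone, DDX21, NPM1, NCL and NOLC1, which encode nucleolar proteins, rose, and POLR1C, EMG1, TAF1C and PNO1 fell. DDX21, an RNA helicase, stood at 308 ± 20.8 and 218 ± 18.4 CPM (log2 difference 0.50, SE 0.086). In the list for translation and decay of maternal mRNA (44 members, mean 0.039, adjusted p = 0.188) the terminal uridylyltransferase gene TUT7 (0.43, SE 0.095), the deadenylation factor gene PAN3 (0.39, SE 0.092) and the exonuclease gene XRN1 (0.46, SE 0.11) rose adjusted over the list alone. BTG4, a deadenylation adaptor, at 1068 ± 71.7 and 889 ± 65.0 CPM, did not pass. Among oocyte transcription factors (12 members, mean -0.043, adjusted p = 0.730), TFAP2C rose with a difference of 0.64 (SE 0.11) and FIGLA, a regulator of zona genes, fell by 0.51 (SE 0.10), both adjusted over the list alone. In the maternal effect list (14 members, mean -0.050, adjusted p = 0.327), CTCF rose (0.33, SE 0.078) and PADI6 fell by 0.32 (SE 0.082) by the same adjustment, and ZAR1 did not pass (-0.23, SE 0.085). The antioxidant list (27 members, mean -0.11, adjusted p = 0.203) had PRDX4, an endoplasmic reticulum peroxiredoxin, as the member that fell adjusted over the list alone, by 0.74 (SE 0.14). In the list for contact between oocyte and cumulus cells (25 members, mean -0.029, adjusted p = 0.560), the membrane linker gene RDX (0.32, SE 0.065) and the cadherin gene CDH1 (0.35, SE 0.079) rose by that adjustment. In all 6 libraries this contact list deviated with the sign of the granulosa and cumulus markers (correlation 0.980). No member of these lists passed over all genes.

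No member passed either adjustment in the remaining lists for oocyte and cell physiology. DNA repair had a mean of 0.056 (42 members, adjusted p = 0.0935 by camera), with TP53BP1 at 0.40 (SE 0.096) and ATM at 0.43 (SE 0.12). Fatty acid and lipid droplet genes had a mean of -0.13 (41 members, adjusted p = 0.159), with CPT2 at -0.39 (SE 0.087) and ACSL3 at 0.32 (SE 0.080). Receptors and SMADs of the TGF-beta family had a mean of 0.020 (24 members, adjusted p = 0.139) and passed without large-follicle library 1, without small-follicle library 1 and at 5 CPM (adjusted p = 0.0457, 0.0405 and 0.0339 by camera). This TGF-beta list deviated with the sign of the granulosa and cumulus markers in 5 of 6 libraries (correlation 0.841). Glycolysis had a mean of -0.092 (20 members, adjusted p = 0.203) and the proteasome 0.0070 (35 members, adjusted p = 0.558). Cholesterol synthesis had a mean of 0.019 (24 members, adjusted p = 0.730), apoptosis -0.038 (24 members, adjusted p = 0.730) and signalling of meiotic arrest by cyclic nucleotides -0.022 (19 members, adjusted p = 0.898). The median, mean and test differed in sign for oocyte transcription factors, ribosome biogenesis, cholesterol synthesis, contact with cumulus cells, and blood and immune markers.

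Summed markers of other ovarian cells did not differ between the groups beyond the spread of the libraries. The summed level of 29 granulosa and cumulus markers was 420, 408 and 584 CPM in large-follicle libraries 1, 2 and 3 and 649, 527 and 351 CPM in small-follicle libraries 1, 2 and 3, a log2 difference of -0.088 (exact two-sided permutation test, p = 0.9). Theca and stromal markers summed to 175 ± 6.65 and 169 ± 12.8 CPM (exact p = 0.6), and blood, immune and endothelial markers to 361 ± 22.2 and 364 ± 10.4 CPM (exact p = 0.9). With 3 libraries against 3 the smallest p such a test can give is 0.1. TEK, at 315 to 351 CPM in each library, made up most of the blood, immune and endothelial sum, and MYH11, at 93.3 to 122 CPM, most of the theca and stromal sum. KITLG and VCAN, at 88.3 to 110 and 80.8 to 124 CPM, varied less between libraries than INHBA. HSPG2 ran from 3.09 CPM in small-follicle library 3 to 79.2 CPM in small-follicle library 1, and GJA1 from 1.56 CPM in large-follicle library 2 to 19.6 CPM in small-follicle library 1. Such markers differed more between libraries than the granulosa and cumulus sum did. INHBA, a subunit of activin and inhibin, was at 64.9 CPM in large-follicle library 3 and 54.7 and 41.0 CPM in small-follicle libraries 1 and 2, against 17.4, 27.97 and 9.04 CPM in the other libraries. As sets against all other genes these lists did not pass (means -0.16, -0.15 and -0.010 over 23, 12 and 8 tested members; adjusted p = 0.516, 0.898 and 0.560 by camera). Without small-follicle library 3 the granulosa and cumulus list passed, with a mean of -0.57 and an adjusted p of 9.78e-04 by camera. Adjusted over the list alone, NR2F2 of the theca list rose (0.65, SE 0.16) and CSF1R of the blood and immune list fell by 0.60 (SE 0.10). GJA4 (-0.70, SE 0.51), FSHR (-0.25, SE 0.89) and COL1A2 (-0.26, SE 0.12) did not pass.

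**Figure D4:**
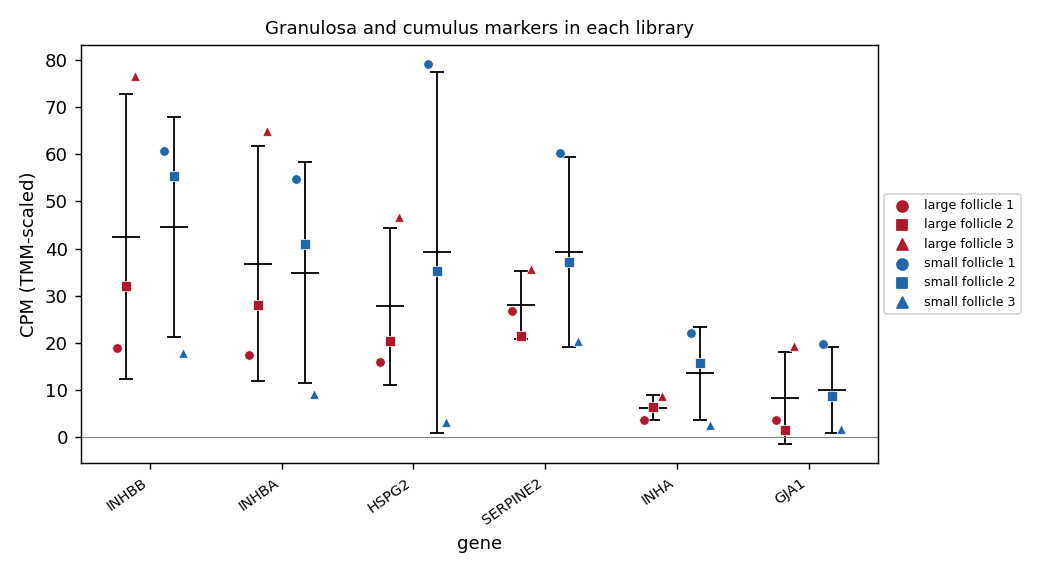
CPM scaled by TMM (vertical axis) of granulosa and cumulus markers, 1 point per library, with red for large and blue for small follicles and black bars for the mean and SD of 3 libraries. INHBA is at 9.04 CPM in small-follicle library 3 and 64.9 CPM in large-follicle library 3, a wider range within each group than between the means of 36.8 and 34.9 CPM.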

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

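The tests of cumulus-cell RNA and of dilution were chosen only after related values were seen, whereas those of depth, of a mixed sample and of gene length were set before their results. In the table, 25 rows whose gene name is a date hold a mean of 0.153% of the reads (0.147% to 0.164% per library), far above the share that a count of 0 allows (at most 3.74e-05% in large-follicle library 3, for counting error only). They were left out of the tests.

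Leaving out large-follicle library 3 raised the count of genes from 9 to 1899. Depth is argued against, since 1637 genes passed when large-follicle libraries 1 and 2 were thinned to the depth of the library left out. Cumulus-cell RNA in that library stays open: it would dilute genes that cumulus cells lack at least as much as others, and 23 germline-restricted genes stood 0.111 (log2) above the fall there of genes higher in large-follicle libraries 1 and 2, corrected for the choice of genes, with a 95% bootstrap interval over genes that covers 0 (-0.00776 to 0.301). Between large-follicle libraries 1 and 2 (0) and the small-follicle mean (1), large-follicle library 3 sat at 0.756 (interval 0.708 to 0.807) over those higher genes. Over genes lower in large-follicle libraries 1 and 2 it sat at 0.607 (0.535 to 0.679). Dilution can lower the higher genes as well, so their position decides nothing. The position over the zona list, 0.188 (interval -0.859 to 0.562), was too uncertain to decide. Small-follicle library 3 sat at 0.796 (0.778 to 0.811) on a scale ending at small-follicle libraries 1 and 2 (large-follicle library 3 at 0.689), but as 1 library outside the pattern it decides nothing on cumulus-cell RNA. Over the 500 genes ranked without it, large-follicle library 3 sat at 0.701 (interval 0.640 to 0.745), against at most 0.450 for any other library held out. A mixed or mislabelled pool could give this position, as could untested variation between pools of large-follicle oocytes. Neither a mix nor a wrong label would by itself set this library outside both groups, as the first principal component did (54.5 against -15.0 to -6.03). It correlated at 0.977 to 0.979 with the small-follicle libraries, which correlated at 0.989 to 0.994 with each other. The position, over genes chosen for the group difference, cannot show such a departure. Small-follicle libraries held out sat at most at 0.236 between their own group (0) and the large-follicle mean (1). That mean includes large-follicle library 3, so these positions cannot decide on a swap with it. On the scale made without both libraries numbered 3, small-follicle library 3 lay nearer to small-follicle libraries 1 and 2 (0.796). Across genes, however, large-follicle library 2 correlated at 0.990 with small-follicle library 3 and at 0.988 with large-follicle library 1.

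Oxidative phosphorylation transcripts, which are short, had lower means and chromatin modifier transcripts, which are long, higher means in large-follicle oocytes. Across genes the log2 difference followed gene length weakly (Spearman 0.111, genes not being independent; 0.153, 0.147 and -0.135 for large-follicle libraries 1, 2 and 3). After the length correction the means were -0.136 (from -0.156) and 0.0806 (from 0.107) and both lists stayed past the threshold, which argues against length as the whole cause. The ribosomal protein mean went from -0.105 (SE over genes 0.0212) to -0.0808 (SE 0.0211) and the mitochondrial mean from -0.281 (SE 0.0583) to -0.247 (SE 0.0591), so most of each stayed (76.6% and 87.8%), but both calls, near the threshold before (adjusted p = 0.0272 and 0.0469 by camera), ended at 0.0990. Cumulus-cell RNA stays open for oxidative phosphorylation, whose deviation had the sign of the granulosa and cumulus markers in 5 of 6 libraries: with those markers as a covariate the group difference was -0.138 (95% interval over libraries -0.552 to 0.275), too wide to decide. A difference between follicle sizes stays open as well. Whether ZNF genes were higher in large-follicle oocytes, like chromatin modifiers, was also asked. Their mean was -0.0409 over 249 genes (interval -0.0862 to 0.00435). It met the bound set beforehand by less than its spread, so a rise of ZNF genes stays open. Long nuclear genes in general were not tested.

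Zona and secreted factor transcripts were lower in large-follicle oocytes in every library left out in turn. Gene length is argued against as the whole cause, since the mean was -0.396 after the correction and -0.416 before. Dilution by cumulus-cell RNA would lower all germline-restricted transcripts alike, but the mean of those from the maternal effect and transcription factor lists lay 0.212 above that of the zona and secreted factor ones (interval of 2 SE over genes, 0.0484 to 0.375), which argues against it as the whole cause. A difference between follicle sizes may underlie it as a hypothesis, and GC content and differences between collections of ovaries, which the labels do not give, stay open and were not tested.

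The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. Counting the real split itself, a result as large came from 1 split for the genes past the threshold (real 9, highest other 2), from 2 splits for higher genes (real 2, highest other 2) and from 1 split for lower genes (real 7, highest other 2). For gene lists it came from 4 splits, the real one among them (real 6, highest other 11). The split with 11 lists set large-follicle libraries 1 and 2 and small-follicle library 3, those with the lowest sums of cumulus markers, against the rest. The 3 others of these 4 gave 7 to 11 lists, and all 3 had large-follicle libraries 1 and 2 on one side.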

How the results depend on the processing

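Thinning and the length correction were chosen only after the results were seen. The 9 genes were all called by DESeq2, limma-voom and edgeR's likelihood ratio test too, but how many genes passed depended on nearly every setting. In simulated counts edgeR recovered 32 of 67 genes changed 1.5-fold, so a gene that did not pass can still differ by that much or more. Recovery in the real data may be lower than in the simulated counts. POLR1C, at 0.923 CPM in large-follicle and 2.90 CPM in small-follicle oocytes, differed 2.80-fold and did not pass (adjusted p = 0.0849 by edgeR). Counts are given as total, higher and lower in large-follicle oocytes. DESeq2 called 722, 400 and 322, the likelihood ratio test 622, 299 and 323, and voom 109, 38 and 71. DESeq2's size factors in edgeR gave 0, 0 and 0 (2525 genes at an unadjusted p under 0.05), and library size alone gave 14, 2 and 12. No filter gave 52, 9 and 43 and at least 5 CPM gave 20, 2 and 18. Limma-trend on log2(TPM + 1), with pseudocounts of 0.1 and 0.5, without a filter and at a TPM of at least 5, gave 0, 0 and 0 (2052, 2031, 2048, 2381 and 1767 genes at an unadjusted p under 0.05). A log2 difference of at least 1 left 1, 1 and 0, and an adjusted p under 0.1 gave 220, 93 and 127 by edgeR. Thinning all libraries gave 4, 2 and 2 and the length correction 41, 13 and 28. Leaving out each library gave 0 to 1899 genes, 0 to 1124 higher and 0 to 775 lower, with fewer samples in each fit, and 3 to 10 lists. With an estimated correlation and with fry, 0 lists passed. The cause was not tested except where a setting says it.

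The replicate number as a block gave 24, 4 and 20 genes, 7 of them shared with the 9, and 5 lists, the meiotic cell cycle call being the one lost (adjusted p = 0.0641 by camera). Same-numbered libraries did not deviate together (correlations -0.0951, 0.00276 and -0.158), so the numbers are not taken as pairs. Under the block FSHR was at 0.20.

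Among named genes the direction turned for INHBA with library size alone (-0.037) and, when single libraries were left out, for CDK1 (-0.13 to 0.017), MOS (-0.080 to 0.027), UHRF2 (-0.091 to 0.017), FSHR (-0.78 to 1.38) and INHBA (-0.61 to 0.51). None of these genes passed in 6 libraries. Of the other values for named genes, 586 kept their direction and side of the threshold, 117 moved past it and 38 fell behind it. The direction of a list's test turned, with these means, for meiotic arrest (-0.022 with fry, -0.020 thinned), cholesterol synthesis (-0.018 at 5 CPM) and theca markers (-0.20 with library size alone, -0.15 with fry). When single libraries were left out it turned, with these ranges of the mean, for oocyte transcription factors (-0.098 to 0.048), meiotic arrest (-0.075 to 0.060), mitochondrial transcripts (-0.47 to 0.0073), the proteasome (-0.067 to 0.043), cholesterol synthesis (-0.034 to 0.043), granulosa markers (-0.57 to 0.14) and theca markers (-0.21 to -0.10). Without single libraries the difference in summed markers ranged from -0.33 to 0.11 for granulosa, -0.012 to 0.093 for theca and -0.051 to 0.036 for blood cells, and theca markers turned to -0.046 as a median. The cause was not tested.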

Other observations

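The lists of lysosomal, writer and ZNF genes were chosen after the genes that prompted them were seen, and their tests were set before their results. Because PSAP, MFSD12 and NAAA, which act in lysosomes, were among the genes with the smallest p and lower in large-follicle oocytes, 65 other lysosomal genes were tested. They had a mean log2 difference of -0.11 (SE over genes 0.025; camera p = 0.00656 with a preset correlation), and with an estimated correlation p was 0.136. Without single libraries the preset p ranged from 0.00130 to 0.0530. The cathepsin genes CTSF (-0.57, SE 0.13) and CTSD (-0.42, SE 0.10) and the proton pump accessory gene ATP6AP1 (-0.37, SE 0.082) had lower means and SLC17A5 (0.26, SE 0.077) a higher one, and none of these passed over all genes. Lower lysosomal transcripts as a group in large-follicle oocytes may thus be a hypothesis worth a test in other oocytes.

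METTL14 (log2 difference 0.47, SE 0.080) and ZC3H13 (0.48, SE 0.082), both of the complex that methylates adenosines in mRNA, had higher means in large-follicle oocytes and an adjusted p of 0.0762 by edgeR, so neither passed. The 6 other members of the complex had a mean of 0.10 (SE over genes 0.031) with a camera p of 0.0793. A missed threshold over so few genes excludes nothing, so a higher level of the whole complex could be neither shown nor excluded.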
